A study of Homo sapiens with 4 samples.

How the data were processed

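RNA was sequenced from 4 samples of HCT15, an established human colorectal adenocarcinoma line. In 2 of these the cells stably overexpressed NSUN5 from a lentivirus, and in the other 2 they carried the empty vector. Per the labels' protocols, total RNA was extracted with Trizol, messenger RNA was enriched on oligo(dT) beads and libraries were made with an NEBNext Ultra RNA kit and sequenced on an Illumina NovaSeq instrument. The labels give a batch, 1 or 2, and each batch holds 1 library of either group. Nothing in the labels says whether the 2 libraries of a group came from separate transductions, so p-values measure only the spread between these libraries, which may be technical.

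The authors deposited 1 table of 20289 genes with estimated counts and FPKM for each library, per the file headers. The estimated counts were not all whole: between 11.4% and 12.2% of values per library were off a whole number by more than 1e-06. They were rounded to whole numbers before testing. The FPKM values were deposited by the authors as normalized values, and served for 1 alternative only. The aligner, the quantifier, the genome build and the annotation are not given in the sources used here. The strand setting of the counting is not given there either, so overlapping and antisense genes cannot be told apart. NSUN5 has 2 close pseudogenes on the same chromosome, NSUN5P1 and NSUN5P2, and its estimated counts were not whole, so reads shared with them could move its level. No value column of the table was left out.

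Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the default low-count filter by group and Benjamini-Hochberg adjustment over the 12553 genes that passed the filter. The threshold was an adjusted p of 0.05. The model held the group only. The fold changes are log2 values of NSUN5 over control, and each SE was taken as the fold change divided by the square root of its F statistic and left out where F was near 0. The model left 2 residual degrees of freedom, and the common biological coefficient of variation was 10.0%. CPM values are TMM-scaled and are given as mean ± SD with n = 2.

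The labels give batch 1 to replicate 1 and batch 2 to replicate 2 of both groups, and equal numbers were read as a shared batch that pairs the libraries, which nothing else in the labels settles. The deviations of same-numbered libraries from their group means correlated at 0.26 across genes, which are not independent replicates, and at 0.11 after correction for GC content and length. A fit with the batch as a term is called the paired fit. It leaves 1 residual degree of freedom, its estimate of the prior degrees of freedom was infinite, and its p-values thus rest on all genes of like abundance sharing 1 spread. Its common coefficient of variation was 4.23%.

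The libraries differed along the GC content of their transcripts. A correction was therefore chosen after seeing the data: for each library, natural splines of GC content with 5 degrees of freedom and of log2 length with 4 were fitted to the deviations of log2 CPM and entered as offsets. GC content and length came from the longest coding transcript of each gene in GENCODE 29 on GRCh38, which gave a value for 99.7% of the genes tested. The paired fit with these offsets is called the corrected paired fit. Gene positions are from the same annotation, matched on Ensembl identifiers, and need not be those of the authors' build.

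Before the data were examined, 30 gene lists, the main test, a first set of other settings and the rule for named genes were fixed. The lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 30 lists. GO and KEGG terms paired with genes in the deposited table were tested likewise where 15 to 300 tested genes carried them, which held for 2050 terms. The rule named NSUN5, BRCA2 and BRIP1. It also named the 10 genes with the largest rise and the 10 with the largest fall among genes with a symbol, a mean of at least 1 CPM, an adjusted p under 0.05 and both libraries of one group above both of the other. From each list it named up to 2 members that rose and 2 that fell with the smallest p, or the member with the smallest p where none passed. After the data were seen, these rules were also applied to the paired and the corrected paired fit. Some genes that the rules named are not reported here.

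The settings fixed before the data were examined were median-of-ratios and upper-quartile factors, no low-count filter (at least 1 read in all), a mean count of at least 50, DESeq2 1.42.0, limma-voom, the paired fit, a minimum log2 fold change of 1, limma-trend on log2(FPKM + 1), each library left out, and for lists an estimated correlation and fry. The GC and length correction with and without pairing, paired DESeq2 and limma-voom fits and edgeR's newer quasi-likelihood method were added after seeing the data.

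The pipeline was tested on simulated data for this comparison, with 200 changed genes, 100 of them changed 2-fold and 100 changed 4-fold. Over 12443 genes with independent libraries, the unpaired test recovered 95 of the 2-fold and all 100 of the 4-fold changes and called 16 unchanged genes. With the observed GC and length trend put into the simulated libraries, over 12442 genes, the unpaired test called 411 unchanged genes, the paired fit 1490 and the corrected paired fit 24. The trend was put in with the same splines that the correction takes out, so the low count of the corrected paired fit was built in. These simulated libraries held no batch effect, and the counts do not measure false calls in the real data.

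Library totals ran from 23961112 to 25998199 estimated counts. The replicates of each group were compared over genes with at least 20 counts in the pair, and chi-square per degree of freedom was 13.1 for the control pair and 15.0 for the NSUN5 pair. No library was therefore treated as a duplicate. For genes at 0 in both libraries of a group, a fold is given as a lower bound against a floor of 3 counts over the group, which covers counting error only.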

Results

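The transcriptomes of HCT15 colorectal adenocarcinoma cells with stable lentiviral overexpression of NSUN5 and of empty-vector cells were compared by poly(A)-selected RNA sequencing, with 2 libraries per group. NSUN5 is an RNA methyltransferase that places 5-methylcytosine on ribosomal RNA. The series title concerns doxorubicin resistance through the DNA repair genes BRCA2 and BRIP1. The comparison thus asks which transcripts differ once NSUN5 is raised. The control libraries held 24693720 and 23961112 estimated counts and the NSUN5 libraries 25469322 and 25998199, over 14709 to 14863 detected genes per library.

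NSUN5 mRNA (ENSG00000130305, GRCh38 chromosome 7, 73302517 to 73308867) was higher in both NSUN5 libraries than in either control library. That checks the group labels of all 4, but not their batch numbers. It stood at 25.6 and 22.4 CPM in the control libraries and at 50.5 and 47.7 CPM in the NSUN5 libraries, means of 24 ± 2.3 and 49.1 ± 1.94 CPM (SD, n = 2). The log2 fold change was 1.04 ± 0.11 (SE, edgeR quasi-likelihood test, adjusted p = 0.0461). Within batch 1 it was 0.98 and within batch 2 it was 1.09. The call did not pass with median-of-ratios factors (adjusted p = 0.0637), without a low-count filter (0.148), with a mean count of at least 50 (0.0547) or with the newer edgeR method (0.0519). The corrected paired fit gave 1.18 ± 0.07.

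BRCA2, which acts in the repair of DNA breaks by homologous recombination, and BRIP1, a helicase partner of BRCA1, were both higher in each NSUN5 library than in either control library. BRCA2 (ENSG00000139618, chromosome 13, 32315474 to 32400266) averaged 9.04 ± 3.02 CPM in control and 35 ± 19 CPM in NSUN5 libraries, a log2 fold change of 1.95 ± 0.38 (edgeR adjusted p = 0.0644). BRIP1 (ENSG00000136492, chromosome 17, 61681266 to 61863521) averaged 20.1 ± 5.57 and 43.6 ± 11 CPM, a log2 fold change of 1.12 ± 0.23 (edgeR adjusted p = 0.0654). Neither passed the threshold over all genes, and both had an adjusted p of 0.0115 when adjusted over the list alone, the list being homologous recombination and Fanconi anaemia repair. In the paired edgeR fit both rose, by 1.92 ± 0.10 (adjusted p = 4.31e-82) and 1.12 ± 0.08 (adjusted p = 3.29e-41). These SEs and p-values rest on 1 spread shared by genes of like abundance, not on the spread of these 2 genes. Within batches 1 and 2 the log2 fold changes were 1.63 and 2.11 for BRCA2 and 1.14 and 1.10 for BRIP1. Their transcripts are low in GC content, 36.3% and 37.5%, and the corrected paired fit gave 1.32 ± 0.09 for BRCA2 and 0.65 ± 0.08 for BRIP1. BRCA2 passed unpaired edgeR tests without control replicate 2 (2.36), without NSUN5 replicate 1 (2.42) and without NSUN5 replicate 2 (1.25), and BRIP1 did in the same 3 (1.45, 1.36 and 0.83). Without control replicate 1 neither passed (1.65 and 0.86).

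**Figure D1:**
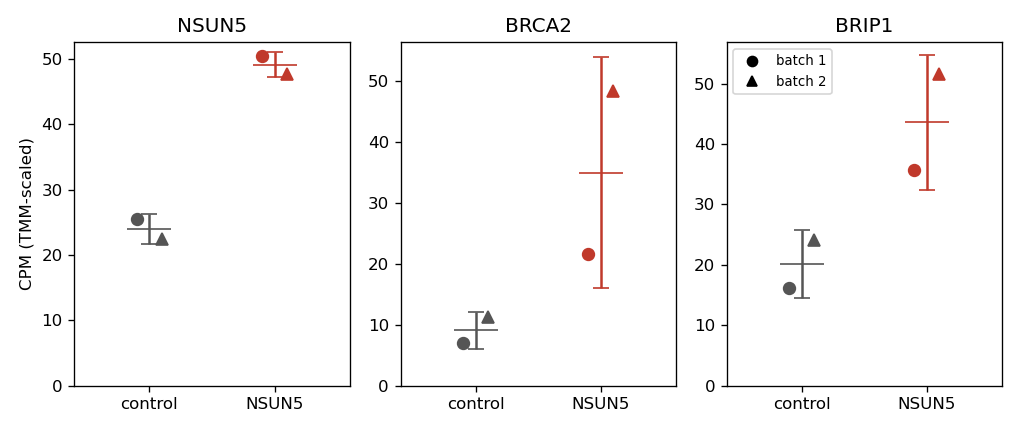
TMM-scaled CPM of NSUN5, BRCA2 and BRIP1 in control and NSUN5 libraries. Circles are batch 1, triangles are batch 2, and horizontal marks with bars are the mean ± SD of 2 libraries. The 2 NSUN5 libraries lie close together for NSUN5 and far apart for BRCA2, where the SD is 19 CPM.

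Over all genes, 2 rose and 6 fell in the unpaired edgeR test of 12553 genes. Besides NSUN5, the gene that rose was KIAA1210, which lies under the 1 CPM minimum of the naming rule and was named after its values were seen. It had 0 counts in both control libraries and 52 and 50 in the NSUN5 libraries, at least 32.1-fold higher. The 6 that fell were EEF1A2, a tissue-restricted translation elongation factor (62.0 ± 8.23 to 16.2 ± 2.98 CPM, log2 fold change -1.93 ± 0.16, adjusted p = 0.0207), PRF1, the pore-forming protein of cytotoxic lymphocytes (-1.75 ± 0.13), and LYPD5 (-1.35 ± 0.12). The others were CD44, a hyaluronan receptor and Wnt target (40.8 ± 6.42 to 17.2 ± 0.391 CPM, -1.25 ± 0.14, adjusted p = 0.0461), the homeobox gene MSX1 (-1.16 ± 0.11) and the RNA-binding protein gene CELF2 (-1.13 ± 0.13). These 8 genes passed in the paired fit and in the corrected paired fit as well. Without a low-count filter 0 of them passed. With median-of-ratios factors, with a mean count of at least 50 and with the newer edgeR method, 4 did in each.

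The number of calls moved widely with the design. The paired edgeR fit called 2891 genes higher and 2512 lower, and the corrected paired fit 1866 higher and 2059 lower, of which 2317 were calls of the paired fit in the same direction. Upper-quartile factors gave 87 higher and 56 lower in the unpaired test, and median-of-ratios factors 0 and 4. Leaving out a library gave 45 higher and 19 lower (control replicate 1), 1527 and 277 (control replicate 2), 1671 and 614 (NSUN5 replicate 1) or 446 and 142 (NSUN5 replicate 2). At an unadjusted p under 0.05 the unpaired test had 3382 genes.

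Fold changes followed GC content, between the groups and between replicates alike. In the lowest of 10 equal groups of genes by GC content (median 37.3%) the median log2 fold change of NSUN5 over control was 0.47, and in the highest (64.5%) it was -0.20. Between the control replicates, 2 minus 1, the medians of the same groups were 0.30 and -0.16, and between the NSUN5 replicates 0.26 and -0.11. They were 0.19 and -0.07 between NSUN5 replicate 1 and control replicate 2. The slope of log2 CPM over GC content, per 10 points and relative to the mean of the libraries, thus fell from control replicate 1 (0.205) over control replicate 2 (0.0419) and NSUN5 replicate 1 (-0.0517) to NSUN5 replicate 2 (-0.195). Across genes, which are not independent replicates, the Spearman correlation of the fold change with GC content was -0.63 between the groups, -0.62 in batch 1, -0.56 in batch 2, -0.62 between the control replicates, -0.51 between the NSUN5 replicates and -0.36 between NSUN5 replicate 1 and control replicate 2. Genes called higher in the paired fit had a median GC content of 40.3%, and those called lower 57.3%.

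**Figure D2:**
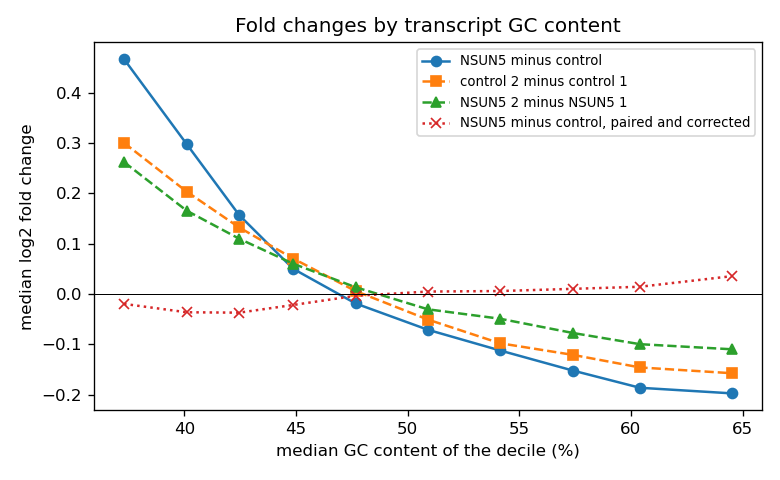
Median log2 fold change against the median GC content (%) of 10 equal groups of genes, for NSUN5 minus control, for the 2 differences between replicates and for the corrected paired fit. The 3 uncorrected lines slope the same way, from 0.47, 0.30 and 0.26 at the lowest GC content to -0.20, -0.16 and -0.11 at the highest.

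Of the 20 genes with the largest changes in the paired fit, EEF1A2, BRCA2 and CCDC186 averaged over 20 CPM and the others under 10. PDGFC, a platelet-derived growth factor, rose from 0.678 ± 0.154 to 3.55 ± 0.0977 CPM (log2 fold change 2.38 ± 0.32, paired edgeR adjusted p = 1.36e-12), and CXCL5, a neutrophil chemokine, from 1.34 ± 0.453 to 5.81 ± 0.861 CPM (2.13 ± 0.24). SPECC1L-ADORA2A (2.62 ± 0.41), ASDURF (2.26 ± 0.35), ZNF117 (2.08 ± 0.27), H2AC18 (2.07 ± 0.37), CCDC88A (2.05 ± 0.16), CCDC186 (1.93 ± 0.09) and ZNF429 (1.93 ± 0.39) rose too. SPECC1L-ADORA2A and H2AC18 had 0 counts in control replicate 1, and within batch 2 the log2 fold changes of SPECC1L-ADORA2A, ASDURF and H2AC18 were 1.72, 1.11 and 0.65. The estimated counts of these genes and of ZNF117 were not whole, so reads shared with other genes could move their levels. FAM189A1 fell from 2.05 ± 0.491 to 0.273 ± 0.0561 CPM (-2.88 ± 0.47, adjusted p = 6.61e-09). ZNF716 (-2.38 ± 0.34), the ephrin ligand gene EFNA2 (-2.18 ± 0.46), RHBDL3 (-2.07 ± 0.30), TBC1D9 (-1.99 ± 0.38), PKDCC (-1.98 ± 0.35), DLGAP1 (-1.98 ± 0.44), AUTS2 (-1.98 ± 0.24), KRTAP3-1 (-1.97 ± 0.22) and EEF1A2 (-1.94 ± 0.08) fell too. In the corrected paired fit each of these genes passed in the same direction, with PDGFC at 2.09, CXCL5 at 1.68, ZNF117 at 1.35, CCDC186 at 1.34 and FAM189A1 at -2.70, while ASDURF had no GC value to correct by. Unpaired, apart from EEF1A2, their adjusted p lay between 0.0563 (PDGFC) and 0.191 (H2AC18).

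Among 911 tested members of the 30 lists, the unpaired edgeR test over all genes called 0 higher and 2 lower, CD44 and MSX1. At an unadjusted p under 0.05 there were 150 higher and 145 lower, DESeq2 called 74 and 24, limma-voom 0 and 2, and the paired edgeR fit 218 and 265. As sets, 4 lists were higher and 4 lower by camera with its preset correlation. With an estimated correlation no list passed, the lowest adjusted p being 0.832, or 0.917 in the paired and 0.802 in the corrected paired fit, and 0 lists had an unadjusted p under 0.05 in the unpaired fit. By fry, which tests whether a list's genes move one way on balance, 2 lists had an unadjusted p under 0.05 and the lowest adjusted p was 0.0541. In the lists below, gene values are log2 fold changes of the paired fit, each with that of the corrected paired fit after it in brackets. Apart from NDUFS8 and CRABP1, the list members given below for the paired fit also passed in the corrected paired fit, in the same direction. That does not hold for all members that the rules named in the paired fit. FAS (0.51 ± 0.08, corrected 0.15), MDM2 (0.38 ± 0.06, corrected 0.06) and ITGAV (0.38 ± 0.06, corrected -0.06) were among those that did not pass after correction. NDUFA5 turned from 0.37 ± 0.08 to -0.22 ± 0.08.

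The homologous recombination and Fanconi anaemia list was higher as a set (camera adjusted p = 0.00042, and adjusted p = 0.832 with an estimated correlation). Of its 48 members 21 were higher and 1 lower when adjusted over the list alone, against 0 and 0 over all genes, and 27 rose and 2 fell in the paired fit. BRCA2 and BRIP1, which the series title names, are members, so the list is not independent evidence on them. RAD50 of the MRN complex rose by 1.30 ± 0.06 (1.01) and FANCE fell (-0.57 ± 0.10; -0.40) in the paired fit, and BRCA1 was at 0.95 ± 0.07 (0.70). The list's median log2 fold change was 0.29 as measured and 0.14 in the corrected paired fit, with 19 members higher and 3 lower (camera adjusted p = 0.000143). Its members had a median GC content of 43.1%.

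Other repair and damage lists did not pass as sets. In end joining (camera adjusted p = 0.317) 4 of 18 members were higher and 1 lower when adjusted over the list alone, and 8 rose and 2 fell in the paired fit, RIF1 (1.49 ± 0.06; 0.91) and POLQ (1.23 ± 0.07; 0.92) among those that rose. In checkpoint signalling (0.149) the counts were 5 and 1 of 22, and 9 and 1 paired, with ATM (1.22 ± 0.07; 0.75) and TOPBP1 (0.80 ± 0.06; 0.61) up and the phosphatase gene CDC25C (-0.36 ± 0.08; -0.36) down. In excision and mismatch repair (0.791) they were 0 and 0 of 36, with 6 higher and 3 lower at an unadjusted p under 0.05, and 11 and 5 in the paired fit, where PMS1 (0.93 ± 0.10; 0.61) rose and ERCC1 (-0.47 ± 0.06; -0.32) fell. The list of doxorubicin targets, transport and metabolism (0.789) had 3 higher and 0 lower of 29 when adjusted over the list alone. In its paired fit, 8 rose, such as the efflux pump gene ABCB1 (0.70 ± 0.06; 0.55) and the doxorubicin target TOP2A (0.76 ± 0.05; 0.38), and 6 fell, such as NQO1 (-0.28 ± 0.04; -0.30) and AKR1A1 (-0.35 ± 0.06; -0.20). Of 30 p53 targets (0.694), 5 rose and 7 fell in the paired fit, with BTG2 at -0.48 ± 0.10 (-0.41). The excision repair and doxorubicin lists had medians of -0.04 and -0.03, means of 0.06 and 0.06 and an upward camera direction. In the corrected paired fit 4 rose and 0 fell in end joining, 8 and 4 in checkpoint signalling, 9 and 4 in excision and mismatch repair, 6 and 3 in the doxorubicin list and 3 and 7 among p53 targets.

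Cell cycle genes were higher as sets. S phase genes (camera adjusted p = 0.00131, and adjusted p = 0.832 with an estimated correlation) had 14 of 66 members higher and 0 lower when adjusted over the list alone and 31 higher and 3 lower in the paired fit, with USP1 at 0.72 ± 0.06 (0.45) and CASP8AP2 at 1.18 ± 0.09 (0.76). G2 and M phase genes (0.0179, and adjusted p = 0.832 with an estimated correlation) had 14 higher and 1 lower of 60, and 32 and 7 paired, with the kinetochore gene CENPF and the spindle genes ASPM at 1.34 ± 0.07 (0.79) and KIF11 at 0.87 ± 0.06 (0.46) among those that rose. CENPF was at 1.16 ± 0.05 in the corrected paired fit. The S phase list passed in the corrected paired fit too (26 higher and 3 lower, median 0.12 as measured and 0.11 corrected, camera adjusted p = 9.26e-05). The G2 and M list did not pass there (18 and 8, medians 0.14 and 0.05, camera adjusted p = 0.101).

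Translation and respiration genes were lower as sets, with small shifts. Of 79 cytosolic ribosomal protein genes 61 fell and 1 rose in the paired fit, RPLP1 by -0.39 ± 0.05 (-0.34), with a median of -0.21 (camera adjusted p = 4.66e-08, and adjusted p = 0.832 with an estimated correlation). When adjusted over the list alone 0 passed in the unpaired test, where 46 were lower at an unadjusted p under 0.05. Ribosomal protein genes took 7.19% and 6.74% of the counts in control replicates 1 and 2, and 6.14% and 6.02% in NSUN5 replicates 1 and 2. Their share thus differed between the control replicates too, and fell in the library order of the GC slope. Of 75 nuclear genes of oxidative phosphorylation 41 fell and 4 rose in the paired fit, NDUFS8 by -0.37 ± 0.07 (-0.10 ± 0.06, corrected adjusted p = 0.192) and UQCRC1 by -0.31 ± 0.05 (-0.12), with a median of -0.17 (camera adjusted p = 9.63e-05, and adjusted p = 0.832 with an estimated correlation). Ribosome biogenesis genes went the other way, 27 of 67 rising and 4 falling in the paired fit, with NOP58 at 0.81 ± 0.06 (0.56), SDAD1 at 0.70 ± 0.07 (0.42) and NOB1 at -0.30 ± 0.05 (-0.17), and were higher as a set (camera adjusted p = 0.0179, and adjusted p = 0.832 with an estimated correlation). In the corrected paired fit 47 ribosomal protein genes fell and 4 rose, 29 and 1 of oxidative phosphorylation, and 32 ribosome biogenesis genes rose and 5 fell. The corrected medians were -0.11, -0.10 and 0.14, all past the camera threshold with its preset correlation. The ribosome biogenesis call did not pass without control replicate 2 (adjusted p = 0.0538) or without NSUN5 replicate 2 (0.254). Of 13 mitochondrially encoded genes (0.451), MT-CO1 rose by 0.20 ± 0.04 (0.20) and MT-ND3 fell (-0.42 ± 0.05; -0.60) in the paired fit.

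Wnt target and intestinal stem cell genes were lower as a set (median -0.19, camera adjusted p = 0.000941, and adjusted p = 0.832 with an estimated correlation). CD44 and MSX1 fell over all genes, 5 of 23 members were lower when adjusted over the list alone and 11 in the paired fit, and 0 were higher in either. Immediate early genes, which respond within minutes to growth signals, were lower as well (-0.16, camera adjusted p = 0.00122, and adjusted p = 0.832 with an estimated correlation). Of their 35 members 17 fell and 0 rose in the paired fit, such as the phosphatase genes DUSP5 (-0.97 ± 0.06; -0.82) and DUSP4 (a member of the same family, -0.93 ± 0.12; -0.86) and CCN1 (-0.51 ± 0.06; -0.44). In the corrected paired fit the Wnt list passed (8 lower and 0 higher, median -0.11, adjusted p = 0.0443) and the immediate early list did not (13 and 2, median -0.10, adjusted p = 0.101). The latter also missed the threshold without NSUN5 replicate 2 (adjusted p = 0.0878).

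**Figure D3:**
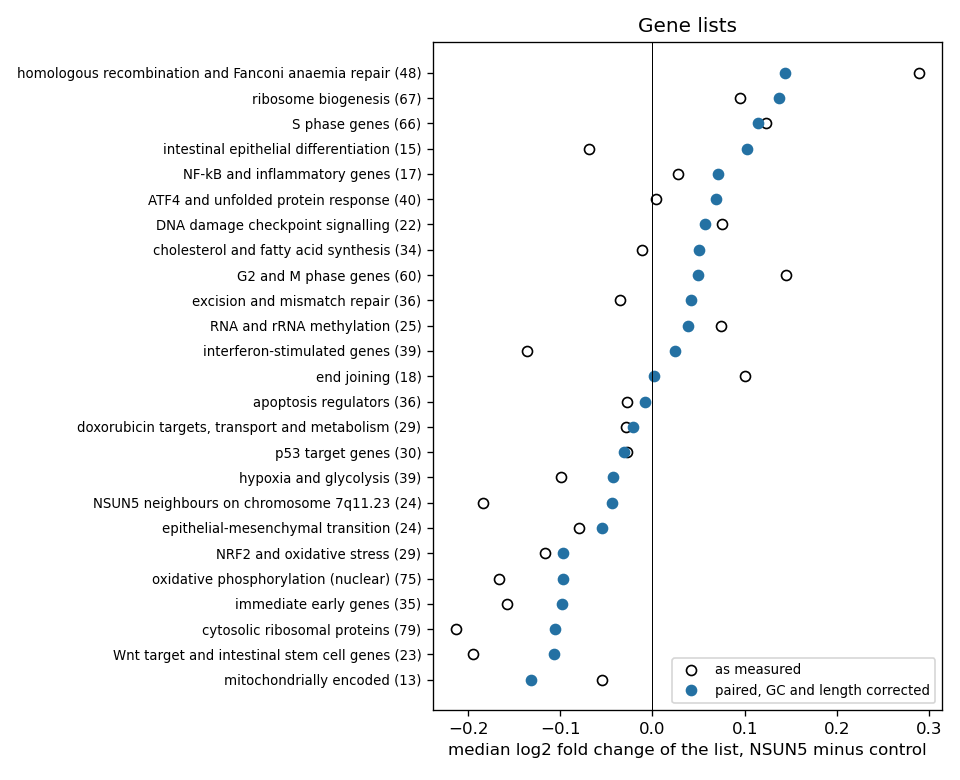
Median log2 fold change of NSUN5 over control for the lists with at least 10 tested members, with the number of tested members in brackets. Open circles are the unpaired fit as measured and filled circles the corrected paired fit. The homologous recombination list has the highest median as measured (0.29) and cytosolic ribosomal proteins the lowest (-0.21).

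The remaining lists did not pass by camera, and over the 22 lists that did not pass the adjusted p lay between 0.0946 and 0.988. The median and mean differed in sign for the interferon (-0.14 and 0.00), lipid synthesis (-0.01 and 0.04), epithelial differentiation (-0.07 and 0.10) and apoptosis (-0.03 and 0.01) lists. Single members passed in the paired fit. The cystine transporter gene SLC7A11 (1.04 ± 0.06; 0.41) and the chaperone gene HSP90B1 (0.47 ± 0.05; 0.29) rose in the ATF4 and unfolded protein list, ELOVL6 (0.86 ± 0.07; 0.59) in lipid synthesis, and NFE2L2, which encodes NRF2 (0.70 ± 0.06; 0.67), in the oxidative stress list. Of apoptosis regulators BIRC2 rose by 0.81 ± 0.07 (0.39) and BCL2L1 fell (-0.42 ± 0.05; -0.27). Of interferon-stimulated genes PARP14 rose by 0.47 ± 0.06 (0.32), and the antigen presentation genes HLA-B (-0.66 ± 0.07; -0.47) and HLA-C (-0.45 ± 0.06; -0.25) fell. Of NF-kB and inflammatory genes IL32 fell (-0.78 ± 0.11; -0.62). The epithelial genes VIL1 (0.50 ± 0.07; 0.39) and CDH17 (1.24 ± 0.24; 1.11) rose, KRT19 fell (-0.38 ± 0.05; -0.16), and the hypoxia gene NDRG1 was at -0.38 ± 0.06 (-0.21). Of RNA methylation genes METTL14 rose by 0.64 ± 0.09 (0.21) and NOP2 fell (-0.37 ± 0.06; -0.23). The 24 tested neighbours of NSUN5 on its chromosome arm had a median of -0.18, with CLIP2 at -0.51 ± 0.06 (-0.30). BAZ1B rose by 0.22 ± 0.05 (0.24), and TRIM74, which averaged 0.687 CPM with counts that were not whole, by 2.48 ± 0.57 (2.69). In the paired fit 2 of these neighbours rose and 9 fell, and unpaired 1 was higher and 0 lower when adjusted over the list alone. Their list was lower as a set without NSUN5 replicate 1 (camera adjusted p = 0.0212) and with a mean count of at least 50 (0.0122), and its median GC content was 59.1%. In the corrected paired fit its median was -0.04 (camera adjusted p = 0.855).

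Lists of markers of other cell types did not pass as sets. Of fibroblast markers 2 were tested (camera adjusted p = 0.211), of immune markers 4 (0.791), of endothelial markers 3 (0.936) and of the kidney line used to make lentivirus 5 (0.305). The most abundant of each averaged 13.8, 14.6, 14.5 and 55.5 CPM. In the paired fit 0 of these markers rose, and 1 fibroblast, 1 immune and 2 kidney line markers fell, ACTA2 by -0.47 ± 0.11 (-0.36), CD68 by -0.48 ± 0.11 (-0.35), HOXD13 by -0.68 ± 0.21 (-0.61) and CRABP1 by -1.61 ± 0.69 (-1.37, corrected adjusted p = 0.130). In the corrected paired fit the kidney line marker GAL passed as higher (0.15 ± 0.06, adjusted p = 0.0487), against -0.10 ± 0.12 as measured.

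Of 2050 GO and KEGG terms carried by the table, camera called 9 higher and 33 lower with its preset correlation, 26 and 38 in the paired fit, and 16 and 11 in the corrected paired fit. With an estimated correlation 0 terms passed (lowest adjusted p = 0.971), and 1 had an unadjusted p under 0.05. By fry 0 passed, and 338 had an unadjusted p under 0.05. With the preset correlation, terms that were higher included DNA double-strand break processing (15 genes, median 0.52, adjusted p = 0.00772), which did not pass in the corrected paired fit (median 0.19, adjusted p = 0.110), homologous recombination repair (78 genes, 0.13, 0.0235) and replication fork processing (31 genes, 0.41, 0.0362), which did (0.0416 and 0.0149, medians 0.11 and 0.18). Terms that were lower included the cytosolic ribosome (76 genes, -0.20, 1.22e-05) and oxidative phosphorylation (128 genes, -0.15, 0.0116), which passed there too (0.00417 and 0.0416, medians -0.11 and -0.10), and the extracellular matrix (105 genes, -0.27, 0.00154), which did not (-0.14, 0.0908).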

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

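The direction of NSUN5, BRCA2 and BRIP1 held under each setting that gave a value, and so did that of 85 of 87 other genes. Calls did not hold. These 87 were picked for the text and are not all the genes that the rules named. GAL (-0.10) turned with the GC and length correction (0.15, and 0.15 with the replicate block) and without control replicate 1 (0.0751), and was at -0.223 without control replicate 2. ZNF566 (0.42) turned with the correction (-0.0669, and -0.0649 with the replicate block). Some genes that the rules named outside these 87 turned too. With the unpaired correction ITGAV went from 0.37 to -0.06, NDUFA5 from 0.38 to -0.22, LBR from 0.16 to -0.28 and FBL from -0.14 to 0.05. The GC and length correction with or without pairing, the paired DESeq2 and limma-voom fits and edgeR's newer method were chosen after seeing the data. Where a library was left out, 1 arm held a single library that is assumed to vary like the other arm. Median-of-ratios factors and the newer edgeR method tested the same number of genes as the unpaired test, and what moved the calls was not tested.

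The 2 genes higher and 6 lower became 0 higher with median-of-ratios factors, 87 and 56 with upper-quartile factors, 0 and 0 without a low-count filter (edgeR, 3297 genes at an unadjusted p under 0.05), 0 higher with a mean count of at least 50 and 0 higher with the newer edgeR method. DESeq2 called 931 and 157, limma-voom 5 higher, and limma-trend on log2(FPKM + 1) 4 higher. The replicate block gave 2891 and 2512, or 1622 and 575 in DESeq2 and 2754 and 2294 in limma-voom. The GC and length correction gave 389 and 327, and 1866 and 2059 with the replicate block. With a library left out the counts ran from 45 to 1671 higher and from 19 to 614 lower.

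The 4 lists higher and 4 lower became 0 and 0 with an estimated correlation and 0 and 0 by fry. The 9 GO and KEGG terms higher and 33 lower became 0 and 0 in both of these tests, 26 higher with the replicate block, 19 higher on FPKM, 4 and 6 with the GC and length correction, and 16 and 11 with the correction and the replicate block. With a library left out they ran from 4 to 29 higher and from 16 to 31 lower.

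NSUN5 missed the threshold with median-of-ratios factors (1.05), without a low-count filter (1.03), with a mean count of at least 50 (1.03) and with the newer edgeR method (1.04), and ran from 0.96 to 1.14 with a library left out. BRCA2 passed in DESeq2 (1.96), with the replicate block (1.92), with the GC and length correction (1.33), with both (1.32), and in the DESeq2 (1.90) and limma-voom (1.94) fits with the replicate block. It ran from 1.25 to 2.42 with a library left out and was lowest on log2(FPKM + 1), at 1.17 (adjusted p = 0.116). BRIP1 passed in the same fits, at 1.13, 1.12, 0.65, 0.65, 1.13 and 1.12, ran from 0.83 to 1.45 with a library left out and was at 0.91 on log2(FPKM + 1) (adjusted p = 0.112). Of the 87 other genes picked for the text, 79 passed with the replicate block that had not passed without it. Apart from the calls given beside the results, the replicate block changed no set call among the 30 lists.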

Other observations

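The tests of the zinc finger stretch, of BRCA2 and BRIP1 against genes of like GC content and of the S phase list were written before their results were seen. The 3 tests of the GC trend and those of S phase as the whole of the rise were chosen after. The zinc finger stretch was first noticed among the named genes, which its test leaves out, so it is a hypothesis drawn from the same data. The reading of BRIP1 was changed after its percentile was seen, from within the range of like genes to undecided, because the corrected fold change, which the written prediction also names, was not near 0. Besides KIAA1210, 3 genes had 0 counts in both control libraries and at least 15 in each NSUN5 library, and 0 genes the reverse. MTTP, which loads lipid onto lipoproteins (chromosome 4), had 26 and 29 counts, at least 17.3-fold higher, and the peptide hormone gene RLN3 (chromosome 19) 39 and 51, at least 28.4-fold higher. A gene with no symbol, ENSG00000262526 on chromosome 17, had 20 and 22, at least 13.2-fold higher. MTTP and RLN3 did not pass over all genes in the unpaired edgeR test (adjusted p = 0.0636 and 0.0563).

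After the GC and length correction, zinc finger genes of 1 stretch of chromosome 19 were lower together. ZNF571, ZNF540, ZFP82 and ZNF461, named in the corrected paired fit with log2 fold changes of -2.36, -2.08, -2.08 and -2.03, lie between 36383120 and 37614097 on GRCh38. The other 10 tested zinc finger genes of that stretch had a median of -0.54 (95% bootstrap interval -0.76 to -0.28), 9 of them lower and 8 past the threshold as lower, ZNF850 at -1.42, against 0.08 for 157 outside it on the same chromosome (permutation test, one-sided p = 0.00045). Without correction the medians were -0.20 and 0.15 (permutation test, one-sided p = 0.0142), 7 of the 10 were lower, 0 passed in the unpaired edgeR test over all genes, and in the paired fit 3 passed as lower, ZNF850 at -1.16, and 2 as higher, ZNF566 (0.42, corrected -0.06, adjusted p = 0.0224) and ZNF585B (0.41, corrected 0.24, adjusted p = 0.0143). The permutation tests and the bootstrap treat genes as independent, though some here overlap, such as ZNF567 and ZNF850. They do not measure the spread between libraries or lines. A regional change, such as silencing of the cluster in one of the stable lines, is a candidate explanation, and a difference between lines that arose apart from NSUN5 could give the same values, as could reads shared among these related genes, which were not tested.

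The GC trend separates replicates as well as groups. Its Spearman correlation was -0.51 between the NSUN5 replicates and -0.62 between the control replicates, which carry one construct each, and weaker, at -0.36, between NSUN5 replicate 1 and control replicate 2, so GC-dependent differences between library preparations may account for at least part of it. The level of NSUN5 mRNA alone would give replicates like slopes, but the larger difference between replicates was 0.661 times that between groups (95% bootstrap interval 0.632 to 0.691). That interval, like those below, resamples genes and does not measure the spread between libraries. Loss of long transcripts from less intact control RNA, as the whole of the trend, would leave none with length held, but the partial Spearman correlation with GC content was then -0.60 (-0.61 to -0.59). The length held was that of the longest coding transcript, which need not be the one expressed, so other effects of RNA integrity are not excluded. A smaller part from such loss stays open, since fold changes correlated with length at 0.25 (0.30 in batch 1, 0.17 in batch 2, 0.27 between the control and 0.06 between the NSUN5 replicates) and, GC content held, at 0.0627 (0.0443 to 0.0798), and with 2 libraries per group a part that belongs to NSUN5 stays untested.

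The estimated rise of BRCA2 was larger than that of 198 of the 200 genes nearest to it in GC content and length. That of BRIP1 cannot be told apart from the range of like genes. BRCA2 lay at the percentile 99.0 of the 200 tested genes nearest to it in GC content and length, whose median was 0.59. That percentile ranks the estimate of 1.95 and leaves out its SE of 0.38, so it does not settle whether the rise goes beyond the trend. BRIP1 lay at the percentile 91.0 of its own 200, median 0.49, and its corrected fold change of 0.65 ± 0.08 keeps it open, since a correction of the mean trend leaves the spread of such genes in place. A larger share of cells in S phase could give the median of 0.11 over 65 S phase genes, BRCA2 and BRIP1 left out (0.07 to 0.14). The lower bound of BRCA2 in the corrected paired fit, 1.14, was above all 65 (percentile 100, the highest being CASP8AP2 at 0.76). That bound rests on the paired SE of 0.09, and the unpaired test with the same correction gave 1.33 ± 0.26. The comparison thus does not exclude a larger S phase share as the whole of the rise of BRCA2. For BRIP1, whose lower bound of 0.50 is at the percentile 92.3, that stays open too. Whether NSUN5 itself raises BRCA2 was not tested, because the labels leave open whether each group is more than 1 stable line.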
